A study of Homo sapiens with 60 samples.

How the data were processed

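Messenger RNA of SW1783 cells was sequenced after 24 h with vehicle or with an ethanol extract of a medicinal herb, at 3 doses per extract. The library kit was directional and reads were paired with 100 bases each, per the labels' protocols, which also state an RNA integrity number above 7. The sample labels give 0.1% dimethyl sulfoxide as vehicle, while the series text gives 2%. Doses were set, per the series text, to the concentration that inhibits growth by 20% where this lay under 500 µg/mL, which applied to Glycyrrhizae Radix.

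The values used were expected counts per gene deposited by the authors, made with Trim Galore 0.6.5, FastQC 0.11.9, STAR 2.7.3a and RSEM 1.3.3 on GRCh38, per the submitters' processing notes. The role of each tool, the annotation release and the strand setting of the counting are not given in the sources used here. Estimated counts divide reads that match several genes between them, so values of paralogs, pseudogenes and multicopy genes are uncertain. The same holds for overlapping and antisense genes if strand was not used. Of the values, 9.19% were not whole, and all were rounded to whole numbers. The table held 60675 gene identifiers, of which 56558 were matched to a current symbol and 57055 were found in GENCODE release 29, the source of coordinates. Of 279 columns, 60 matched 1 sample each by name and were used, and 219 were not used here.

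Libraries were grouped by extract and dose as labelled. The 19 groups with at least 2 libraries (54 libraries) entered 1 fit with edgeR 4.0.16 (R 4.3.3): trimmed-mean scaling, the default filter on low counts, which left 17936 genes, and the quasi-likelihood test, with 35 residual degrees of freedom. Scaling factors ran from 0.906 to 1.02 and the common dispersion was 0.00622, a biological coefficient of variation of 7.89%. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Comparisons were each dose against vehicle, high against low dose, and extracts whose sample numbers begin alike (a set) against each other at the high dose; low doses were compared across extracts. CPM are counts scaled to library size, as mean ± SD over libraries. Log2 changes are fitted, ± SE. On simulated data with the depth and spread of Glycyrrhizae Radix high against vehicle, the fit recovered 59.7%, 74.6% and 95.5% of genes changed by 0.5, 1 and 2 on the log2 scale, with 6.7% false calls. For Rehmanniae Radix Preparata these were 49.3%, 70.1%, 95.5% and 3.38%, and for Paeoniae Radix high against low 62.7%, 77.6%, 83.3% and 3.87%.

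Before the data were examined, 31 gene lists (462 genes) were fixed, along with the design, the alternatives and the rule for named genes. Lists with at least 4 tested genes were tested with camera of limma 3.58.1 at a preset correlation of 0.01, which left out endothelial and epithelial markers, and again with an estimated correlation. The lists were: ATF4 amino acid stress, NRF2, heat shock, ER chaperones, autophagy and lysosome, hypoxia and glycolysis, p53, FOXO, NF-kB, interferon, immediate early, glucocorticoid receptor, aryl hydrocarbon receptor, PPAR, LXR, cholesterol, fatty acid synthesis, metallothioneins, G2 and mitosis, DNA replication, histones, matrix and TGF-beta, metalloproteinases, mitochondrially encoded and ribosomal protein genes. Markers of astrocytes, neurons, oligodendrocytes and microglia completed them. Member counts use the adjustment over all genes and, separately, one over the list. A list not mentioned for a comparison was not called in it. Mitochondrial and ribosomal shares are percentages of all counts.

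Named genes outside the lists have a mean of at least 5 CPM, an adjusted p under 0.05 and every treated library beyond every library of the other group. They are the 6 largest rises and falls at the high dose, 4 for high against low dose and pairs of extracts, 3 at the medium and low dose, and 5 for single libraries. The 3 members with the smallest p of each called list, whatever their level, were added for the high dose against vehicle. Some genes that this rule takes are not reported here. Other members named for high against low dose were chosen after their values were seen. For single libraries, log2 changes used a prior count of 2, and list medians were set against 10000 random lists matched in 20 expression bins. Alternatives were other scaling (relative log expression), DESeq2 1.42.0, no filter, a replicate block, fits of the compared groups alone and leaving out each library. Robust fitting and leaving out the outlying library were added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Intervals and floors cover counting error only.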

Results

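RNA was sequenced from SW1783 cells, an established human astrocytoma line, after 24 h with extracts of 8 medicinal herbs or with vehicle. Each herb had been extracted in 70% ethanol and was given at 3 doses, 500, 100 and 20 µg/mL (high, medium and low), except Glycyrrhizae Radix (licorice root) at 300, 60 and 12 µg/mL. Panax Ginseng, Angelicae Gigantis Radix (Korean angelica root), Paeoniae Radix (peony root) and Cnidii Rhizoma had 3 libraries per dose, as had Glycyrrhizae Radix. Rehmanniae Radix Preparata (prepared rehmannia root) had 2 per dose, Poria Cocos (a fungus) and Atractylodis Rhizoma 1 per dose, and the dimethyl sulfoxide vehicle 3. All titles name the same batch. The sample numbers begin alike for pairs of extracts, called sets here, and differently for vehicle. No label says what this part stands for, and vehicle cannot be told apart from it. Comparisons of high with low dose lie within a set and do not use the vehicle. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

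The 60 libraries held 17.8 to 33.72 M (mega) estimated counts (median 27.73 M) and 21978 to 24231 genes with a count. Vehicle libraries held 26.1 to 27.91 M. By dose from high to low, the ranges were 20.62 to 31.28, 25.23 to 31.31 and 25.87 to 30.65 M for Glycyrrhizae Radix, and 19.76 to 33.17, 25.26 to 30.4 and 26.05 to 33.72 M for Panax Ginseng. They were 21.3 to 23.99, 18.03 to 20.59 and 22.95 to 29.05 M for Angelicae Gigantis Radix, and 20.05 to 27.46, 26.54 to 30.65 and 27.84 to 29.83 M for Paeoniae Radix. Cnidii Rhizoma had 20.66 to 29.57, 22.8 to 27.62 and 28.63 to 29.55 M, and Rehmanniae Radix Preparata 22.91 to 28.22, 26.47 to 28.63 and 17.8 to 23.61 M. The single libraries held 28.9, 27.94 and 30.94 M for Poria Cocos and 31.79, 28.15 and 28.75 M for Atractylodis Rhizoma. Mitochondrially encoded genes took 3.957 to 7.601% of the counts, with 6.56 to 6.995% in the vehicle libraries.

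Libraries of a group were close to each other in all but 1 case. Over 51 pairs of libraries from the same group, log2 expression correlated across genes with a median r of 0.9919 and a lowest r of 0.9583. All pairs differed by more than sampling noise (lowest chi-square per gene 1.823), so none was taken for a library deposited again. The outlying library was replicate 2 of Angelicae Gigantis Radix at the medium dose. It correlated with its fellow libraries at r = 0.958 and 0.959, against 0.989 or more in all other pairs. Of 11234 genes, 1571 (14%) lay over 2-fold from the fellow libraries, against at most 15 in any other group. In this library cytoplasmic ribosomal protein genes took 5.577% of the counts (2.501 to 2.99% elsewhere) and mitochondrially encoded genes 3.957%. It stayed in all tests, and the number of genes called without it is given where it differs by over 1.5 times.

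With Glycyrrhizae Radix at the high dose, genes of amino acid starvation and oxidative stress rose and genes of mitosis, DNA replication and extracellular matrix fell against vehicle (n = 3 in both groups). GDF15 (ENSG00000130513, GRCh38 chromosome 19, 18374731 to 18389176), a cytokine secreted under stress, rose 31.4-fold, from 4.293 ± 0.263 to 134.9 ± 9.13 CPM (mean ± SD), with a log2 change of 4.97 ± 0.12 (SE) and adjusted p = 8.6e-31. KCP (ENSG00000135253, chromosome 7, 128862451 to 128910719), a secreted modulator of bone morphogenetic protein signalling, rose 35.7-fold to 16.62 ± 2.36 CPM. Rises of 13.8-fold for ATP2A3, a calcium pump of the endoplasmic reticulum, 13.6-fold for HKDC1, a hexokinase, and 9.95-fold for the peptide hormone gene ADM2 followed. The largest falls were those of CCL2 (ENSG00000108691, chromosome 17, 34255218 to 34257203), a monocyte chemokine, from 39.97 ± 1.99 to 4.195 ± 0.565 CPM (log2 change -3.25 ± 0.15, adjusted p = 2.7e-21), and of TUBB3, a beta tubulin (4.47-fold lower). The hedgehog-binding protein gene HHIP was 3.85-fold lower. In all, 3995 genes rose and 3735 fell of 17936 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 1209 of them by more than 2-fold.

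By list, 18 of 19 genes of the ATF4 amino acid stress response rose with Glycyrrhizae Radix and 1 fell (camera adjusted p = 1.6e-50). Among them were asparagine synthetase ASNS (7.15-fold, to 433.7 CPM), serine synthesis enzyme PSAT1 (4.81-fold) and pseudokinase TRIB3 (9.27-fold). Of 17 NRF2 antioxidant targets, 15 rose (adjusted p = 2.7e-28), including heme oxygenase HMOX1 (5.22-fold), cystine transporter SLC7A11 (3.28-fold) and glutathione synthesis gene GCLC (2.21-fold). In the autophagy and lysosome list 15 of 18 rose (adjusted p = 1.8e-13), with the cargo receptor SQSTM1 at 2081 ± 46.3 CPM against 546.5 ± 8.08. All 20 genes of G2 and mitosis fell (adjusted p = 2.5e-49), PLK1 by 1.64, AURKA by 1.34 and TPX2 by 1.16 on the log2 scale. DNA replication genes fell in 16 of 20 cases (adjusted p = 1.1e-10), with ribonucleotide reductase subunit RRM2 2.79-fold lower and CCNE2 1.91-fold lower. The matrix and TGF-beta list fell too, in 15 of 20 genes (adjusted p = 1.1e-09), smooth muscle actin ACTA2 being 2.37-fold lower. When adjusted over the list alone, these counts changed only for DNA replication, to 17.

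Smaller lists moved as well with Glycyrrhizae Radix against vehicle. All 7 metallothioneins and related zinc genes rose (adjusted p = 0.0019), MT1E from 28.07 ± 2.17 to 83.55 ± 5.87 CPM, MT1X 2.55-fold and the zinc exporter SLC30A1 1.45-fold. The MT1 and MT2 genes are near-identical copies, so the split between them is uncertain. Of 19 hypoxia and glycolysis genes 13 fell and 3 rose (adjusted p = 6.6e-05), LDHA and PFKFB3 by 1.00 and 0.83 on the log2 scale, while NDRG1 rose 1.85-fold. Replication-dependent histones fell in 8 of 9 cases (adjusted p = 0.0043), and cholesterol genes in 12 of 22 with 1 rise (adjusted p = 0.0028), 13 and 1 adjusted over the list alone. Among 16 NF-kB inflammatory genes 8 fell and 6 rose (adjusted p = 0.0043, direction down; mean log2 change -0.25, and 0.11 without the filter), PTGS2 (cyclooxygenase 2) being 3.26-fold and BIRC3 2.55-fold lower. Neither this list nor the cholesterol list was called between the high and low doses. The p53 target list rose in 8 of 15 genes with 2 falls (adjusted p = 2.3e-05), led by GDF15 and the death receptor gene TNFRSF10B (2.33-fold), both of which other stress factors also induce. Astrocyte and glioma markers fell in 6 of 9 genes with 2 rises (adjusted p = 0.0073), vimentin (VIM) by 0.71 and CD44 by 0.54 on the log2 scale. ER chaperones rose in 10 of 15 genes with 1 fall (11 and 1 adjusted over the list alone), HSPA5 by 0.96 on the log2 scale; this list had adjusted p = 0.0045, and adjusted p = 0.12 with an estimated correlation. FOXO targets had 7 rises and 2 falls among 14 (8 and 2 adjusted over the list alone), with IRS2 2.5-fold higher and TXNIP 3.28-fold lower, at adjusted p = 0.0097 and adjusted p = 0.066 with an estimated correlation.

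Between its high and low doses, Glycyrrhizae Radix changed 6030 genes, 3175 upward and 2855 downward, and 878 by more than 2-fold. GDF15 rose 30.4-fold (log2 change 4.93 ± 0.12, adjusted p = 1.4e-30) and KCP 28.3-fold. CCL2 was 5.71-fold lower, VAV3, a guanine nucleotide exchange factor, 5.26-fold and PTPRC (CD45) 3.63-fold lower. The same lists led: 18 of 19 ATF4 genes rose (adjusted p = 5.4e-72; CHAC1, a glutathione-degrading enzyme, 9.46-fold), as did 15 of 17 NRF2 targets (adjusted p = 1.5e-32), 16 of 18 autophagy genes (adjusted p = 5.9e-19) and 6 of 7 metallothionein genes (adjusted p = 0.00066, 7 adjusted over the list alone). All 20 mitotic genes fell (adjusted p = 2.7e-52), with 17 of 20 replication genes (adjusted p = 1e-17) and 13 of 20 matrix genes (adjusted p = 1.2e-06). Hypoxia genes had 3 rises and 13 falls (adjusted p = 0.00025), p53 targets 9 and 2 (adjusted p = 2.4e-08), FOXO targets 7 and 2 (adjusted p = 0.0058), and ER chaperones 8 rises (9 adjusted over the list alone, adjusted p = 0.00016). Neuron markers were called lower (adjusted p = 0.03) with 2 rises and 2 falls among 6, a mean log2 change of -0.20 and a median of 0.22, so the median goes against the test. Without the filter it had adjusted p = 0.15. Histones fell in 5 of 9 cases (8 adjusted over the list alone) (adjusted p = 0.0093). Astrocyte markers had 2 rises and 5 falls, with adjusted p = 0.048 and adjusted p = 0.062 with an estimated correlation.

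Panax Ginseng at the high dose was followed by higher NRF2 targets, heat shock proteins and inflammatory genes and by lower mitotic and matrix genes than vehicle (n = 3 in both groups). The beta tubulin gene TUBB4A (ENSG00000104833, chromosome 19, 6494319 to 6502848), abundant in neurons and oligodendrocytes, rose 26.7-fold, from 0.4765 ± 0.173 to 12.75 ± 2.21 CPM (log2 change 4.74 ± 0.24, adjusted p = 6.2e-19). HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394214) rose 4.34-fold to 368.5 ± 12.4 CPM, and the aldo-keto reductase genes AKR1C1 and AKR1B10 4.03-fold and 3.69-fold. HSPA1B and HSPA1A, which encode the inducible HSP70, rose 3.95-fold and 3.38-fold. Reads of these 2 copies, like those of the AKR1C family, can be shared. The falls were led by DOK7 (3.45-fold), the ephrin receptor gene EPHB6 (3.11-fold) and MT1E (3.01-fold). In all 2146 genes rose and 2223 fell, 399 of the 4369 by more than 2-fold.

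Of the NRF2 list, 16 of 17 genes rose with Panax Ginseng (adjusted p = 2.8e-67), SLC7A11 2.62-fold. Heat shock proteins rose in 9 of 12 cases (adjusted p = 3.5e-20, 10 adjusted over the list alone), with HSPA8 1.36-fold higher. PPAR fatty acid oxidation targets rose in 8 of 10 (adjusted p = 1.6e-10), namely the lipid droplet protein gene PLIN2 (2.19-fold), ANGPTL4, an inhibitor of lipoprotein lipase (3.33-fold), and CPT1A (1.44-fold). NF-kB inflammatory genes had 10 rises and 1 fall among 16 (adjusted p = 1.2e-06). Interleukin 8 (CXCL8) rose 2.7-fold and IL6 2.09-fold, while CCL2 was 2.32-fold lower. Autophagy and lysosome genes rose in 9 of 18 cases (adjusted p = 6.7e-06, 10 adjusted over the list alone), SQSTM1 2.85-fold and the lysosomal galactosidase GLA 2.02-fold. Genes of G2 and mitosis fell in 17 of 20 cases (adjusted p = 6.3e-15, 20 adjusted over the list alone), PLK1 by 0.61 and TPX2 by 0.43 on the log2 scale. DNA replication fell in 10 of 20 genes (adjusted p = 3.1e-05, 11 adjusted over the list alone), thymidine kinase TK1 being 1.58-fold lower. Matrix and TGF-beta genes fell in 11 of 20 (adjusted p = 1.8e-08, 13 adjusted over the list alone), with THBS1 1.76-fold and CCN2, a matrix-associated signalling protein, 2.04-fold lower. LXR targets fell in 3 of 7 genes (adjusted p = 0.00033, 4 falls and 1 rise adjusted over the list alone), MYLIP, a ubiquitin ligase, 2.01-fold. Of 15 p53 targets 6 rose and 1 fell (adjusted p = 0.0087, 7 and 1 adjusted over the list alone), the cell cycle inhibitor CDKN1A 1.93-fold.

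A further 5 lists were called with Panax Ginseng only under the preset correlation. Immediate early genes had 7 rises and 3 falls among 16 (adjusted p = 0.0098, 9 and 4 adjusted over the list alone; adjusted p = 0.089 with an estimated correlation), DUSP6 being 1.57-fold higher and EGR3 2.25-fold lower. Among metallothioneins 3 fell (adjusted p = 0.021, and adjusted p = 0.11 with an estimated correlation), MT1X 1.51-fold. Glucocorticoid receptor targets had 4 rises and 3 falls (adjusted p = 0.042, and adjusted p = 0.055 with an estimated correlation), DUSP1 being 1.76-fold higher and CRISPLD2 1.59-fold lower. For fatty acid synthesis 5 of 10 genes fell (adjusted p = 0.045, and adjusted p = 0.41 with an estimated correlation), the desaturase SCD 1.29-fold. The ATF4 list had 7 rises and 3 falls (adjusted p = 0.049, and adjusted p = 0.36 with an estimated correlation and 0.083 without the outlying library), ATF3 2.94-fold higher and STC2 1.38-fold lower.

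Against its low dose, the high dose of Panax Ginseng raised 1304 genes and lowered 1287, 280 of the 2591 by more than 2-fold. Without the outlying library of another extract the count was 4236. TUBB4A rose 27.8-fold (log2 change 4.80 ± 0.24, adjusted p = 2.4e-19), CXCL8 5.92-fold and HMOX1 5.08-fold. SCN3A was 3.16-fold and VAV3 2.97-fold lower. NRF2 targets rose in 16 of 17 cases (adjusted p = 1.2e-81, 17 adjusted over the list alone) and NF-kB genes in 15 of 16 (adjusted p = 5.3e-37), among them PTGS2 (1.98-fold) and the cytokine LIF (2.06-fold). Heat shock proteins rose in 7 of 12 (adjusted p = 3.3e-19; HSPA1A 2.82-fold), PPAR targets in 7 of 10 (adjusted p = 1e-16, 8 with 1 fall adjusted over the list alone) and autophagy genes in 10 of 18 (adjusted p = 3.8e-10, 11 adjusted over the list alone). Immediate early genes had 8 rises and 1 fall (adjusted p = 5.5e-10), the ATF4 list 9 and 1 (adjusted p = 5.3e-06), p53 targets 5 rises (adjusted p = 7.9e-06, 6 adjusted over the list alone; CDKN1A 2.25-fold), and glucocorticoid receptor targets 3 and 1 (adjusted p = 0.0011, 4 and 1 adjusted over the list alone). DNA replication fell in 13 genes (adjusted p = 4.1e-09, 17 adjusted over the list alone), mitosis in 12 (adjusted p = 4.6e-09, 14 adjusted over the list alone), and the LXR list had 4 falls and 1 rise (adjusted p = 5.3e-07). Matrix genes fell in 6 cases (adjusted p = 0.0016, 7 adjusted over the list alone; adjusted p = 0.19 with an estimated correlation) and metallothioneins in 3 (adjusted p = 0.01, and adjusted p = 0.075 with an estimated correlation). Aryl hydrocarbon receptor targets rose in 3 (adjusted p = 0.013, and adjusted p = 0.065 with an estimated correlation). Fatty acid synthesis had 1 rise and 2 falls (adjusted p = 0.046, 1 and 3 adjusted over the list alone; adjusted p = 0.42 with an estimated correlation).

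**Figure D1:**
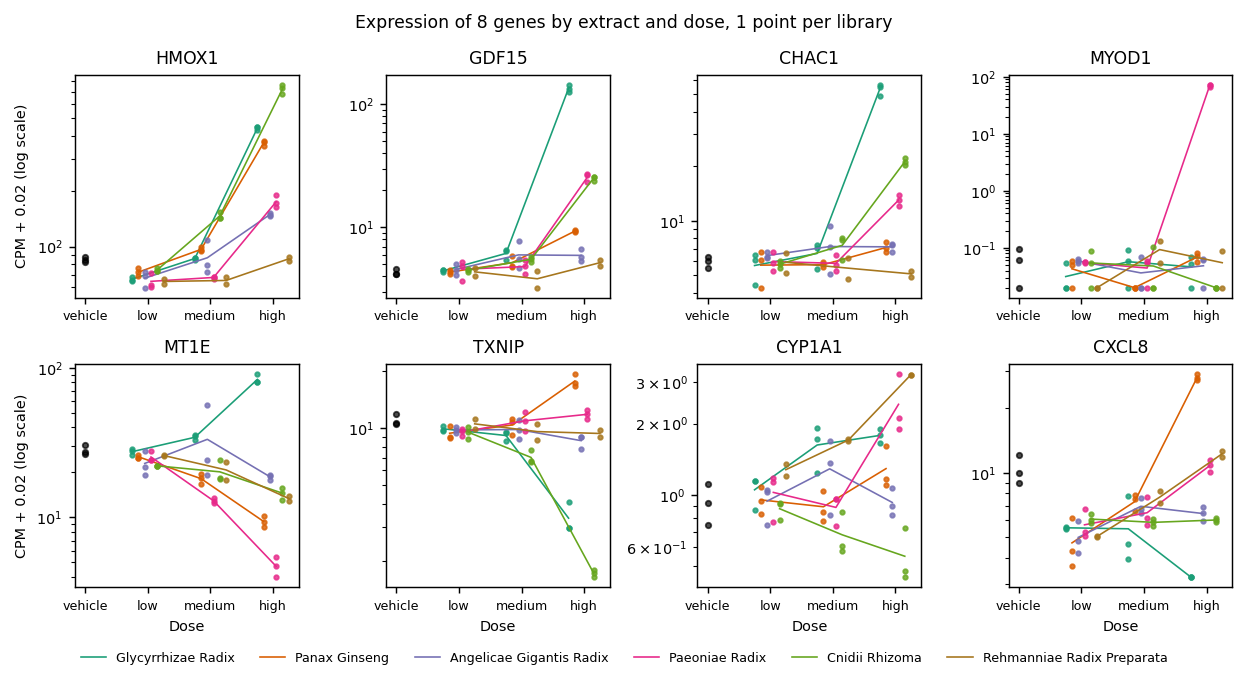
CPM of 8 genes (HMOX1, GDF15, CHAC1, MYOD1, MT1E, TXNIP, CYP1A1, CXCL8) on a log axis (CPM + 0.02) in vehicle and at the low, medium and high doses of the 6 replicated extracts; points are libraries and lines join group means. MYOD1 lies at 67.4 to 72.57 CPM at the high dose of Paeoniae Radix.

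With Angelicae Gigantis Radix at the high dose, NRF2 and PPAR targets rose and cholesterol, inflammatory and mitotic genes fell against vehicle (n = 3 in both groups). The inflammatory and mitotic lists were not called between the high and low doses. ANGPTL4 (ENSG00000167772, chromosome 19, 8363289 to 8374373) rose 2.17-fold, from 21.13 ± 1.19 to 45.78 ± 4.54 CPM (log2 change 1.11 ± 0.11, adjusted p = 6.9e-10), and NEAT1 (ENSG00000245532, chromosome 11, 65422774 to 65445540), the noncoding RNA of paraspeckles, 2.12-fold from 310.7 ± 9.82 to 658.9 ± 7.85 CPM. Larger or similar rises of RN7SL2 (5.03-fold; adjusted p = 0.099 without high replicate 3), HERC2P3 (2.15-fold) and AKR1C3 (1.97-fold) are uncertain, as multicopy genes, pseudogenes or close paralogs. DHRS3 (ENSG00000162496, chromosome 1, 12567910 to 12617731), which reduces retinaldehyde, was 2.77-fold lower, at 10.53 ± 0.0997 against 29.15 ± 1.44 CPM (log2 change -1.47 ± 0.08, adjusted p = 7.4e-17). CCL2 followed at 2.48-fold lower, then ZSWIM4 (2.09-fold) and LIF (1.81-fold). In all 1037 genes rose and 1383 fell, 86 of them by more than 2-fold. These 2420 calls became 4635 without the outlying library and 4294 in a fit of the 6 libraries alone.

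NRF2 targets rose in 12 of 17 cases with Angelicae Gigantis Radix (adjusted p = 3.5e-19, 13 adjusted over the list alone), HMOX1 1.76-fold and the quinone reductase NQO1 1.72-fold. PPAR targets rose in 6 of 10 (adjusted p = 1.5e-15, 7 adjusted over the list alone), PLIN2 1.87-fold. Cholesterol genes fell in 12 of 22 (adjusted p = 6.9e-14, 14 adjusted over the list alone), with INSIG1, which holds back sterol synthesis, 1.66-fold and the synthesis enzyme SQLE 1.39-fold lower. Falls were also called for 9 of 16 NF-kB genes (adjusted p = 2e-11; BIRC3 1.74-fold), 9 of 20 mitotic genes (adjusted p = 1.9e-08, 10 adjusted over the list alone; PLK1 by 0.40 on the log2 scale) and 6 of 12 matrix metalloproteinase genes and inhibitors (adjusted p = 0.001, 7 adjusted over the list alone; PLAU 1.36-fold). None of these lists was called between the high and low doses. Astrocyte markers fell in 2 of 9 (adjusted p = 0.034, 3 adjusted over the list alone; adjusted p = 0.056 without the outlying library and 0.054 without replicate 1 of every group), the transcription factor SOX9 1.3-fold. Matrix and TGF-beta genes had 8 falls and 1 rise (adjusted p = 3.1e-05, 9 and 1 adjusted over the list alone; adjusted p = 0.083 with an estimated correlation), ACTA2 being 1.59-fold lower. Mitochondrially encoded genes fell in 6 of 13 cases (adjusted p = 4.2e-05, 10 adjusted over the list alone; adjusted p = 0.19 with an estimated correlation), and took 5.486 to 5.976% of the counts against 6.56 to 6.995% in vehicle and 5.735 to 6.113% at the low dose. Fatty acid synthesis fell in 4 genes (adjusted p = 0.0092, 7 with 1 rise adjusted over the list alone; adjusted p = 0.3 with an estimated correlation). Immediate early genes had 2 rises and 6 falls (adjusted p = 0.024, 2 and 8 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation), EGR3 being 1.65-fold lower and EGR1 1.55-fold higher. Hypoxia genes had 2 rises and 1 fall (adjusted p = 0.034, and adjusted p = 0.2 with an estimated correlation), and 2 metallothioneins fell (adjusted p = 0.045, 3 adjusted over the list alone; adjusted p = 0.17 with an estimated correlation).

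High and low doses of Angelicae Gigantis Radix differed in 91 genes, 48 higher and 43 lower, 4 of them over 2-fold. ANGPTL4 rose 2.82-fold (log2 change 1.49 ± 0.11, adjusted p = 7.3e-13) and HMOX1 2.22-fold. DHRS3 was 2.48-fold lower, followed by SREBF1 (ENSG00000072310, chromosome 17, 17810399 to 17837002), a regulator of lipid synthesis at 1.6-fold. As lists, NRF2 targets (7 of 17; adjusted p = 7.9e-55, 15 adjusted over the list alone; SLC7A11 1.6-fold), PPAR targets (5 of 10; adjusted p = 3.1e-49, 6 adjusted over the list alone; CPT1A 1.46-fold), ATF4 genes (1 of 19; adjusted p = 8.9e-08, 3 adjusted over the list alone), hypoxia genes (1 of 19; adjusted p = 5.8e-05, 3 adjusted over the list alone) and glucocorticoid receptor targets (1 of 11; adjusted p = 0.00094, but adjusted p = 0.24 without the filter, with the mean log2 change at -0.10 from 0.14) rose. Cholesterol genes (4 of 22; adjusted p = 4.8e-20, 13 adjusted over the list alone; INSIG1 1.24-fold) and LXR targets (2 of 7; adjusted p = 1.2e-06; MYLIP 1.27-fold) fell, and DNA replication was lower as a list (adjusted p = 6e-05, median log2 change -0.08). Fatty acid synthesis fell in 2 genes, SCD 1.34-fold and FADS2 1.23-fold (adjusted p = 5.3e-05, and adjusted p = 0.1 with an estimated correlation), and the matrix list in ACTA2 and CCN2 (adjusted p = 0.00022, and adjusted p = 0.12 with an estimated correlation). Cytoplasmic ribosomal protein genes were lower by a median of -0.07 on the log2 scale (adjusted p = 0.014, and adjusted p = 0.76 with an estimated correlation). The count of 91 was 249 without the outlying library, 165 without the filter on low counts, and 49, 52 and 49 without high replicate 1, high replicate 2 and low replicate 1.

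At the high dose of Paeoniae Radix the muscle regulator MYOD1 appeared, hypoxia, amino acid stress and antioxidant genes rose, and mitotic, metallothionein and interferon genes fell against vehicle (n = 3 in both groups). MYOD1 (ENSG00000129152, chromosome 11, 17719568 to 17722131), a master regulator of skeletal muscle, reached 71.2 ± 2.28 CPM by library size, with 5290 counts in the 3 libraries against 3 in vehicle. The ratio scaled to library size was 1910 (exact 95% interval 654 to 9270, counting error only; adjusted p = 4.1e-27). GDF15 rose 5.96-fold, the peptide hormone gene APLN (ENSG00000171388, chromosome X, 129645259 to 129654937) 5.56-fold from 3.8 ± 0.355 to 21.1 ± 0.275 CPM, and PPFIA4 5.28-fold. The pseudogene NMRAL2P (5.54-fold) shares sequence with other genes and is uncertain. DLGAP5 (ENSG00000126787, chromosome 14, 55148112 to 55191678), a mitotic spindle protein, was 8.83-fold lower, at 11.45 ± 0.458 against 101.1 ± 1.98 CPM (log2 change -3.14 ± 0.05, adjusted p = 6.9e-36). Next came CCL2 (7.34-fold lower), the fatty acid hydroxylase CYP4V2 (6.16-fold), MT1E (5.93-fold) and the centrosomal LRRCC1 (4.93-fold). In all 4001 genes rose and 4159 fell, 1309 of the 8160 by more than 2-fold.

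Hypoxia and glycolysis genes rose in 16 of 19 cases with Paeoniae Radix (adjusted p = 1.7e-28, 18 adjusted over the list alone), NDRG1 4.49-fold and the glucose transporter SLC2A1 2.45-fold to 547.8 ± 5.19 CPM. ATF4 genes had 15 rises and 1 fall (adjusted p = 2.4e-14), TRIB3 3.41-fold and ASNS 2.68-fold, and NRF2 targets 14 and 1 (adjusted p = 4.5e-09), SLC7A11 3.34-fold. Mitotic genes fell in 18 of 20 (adjusted p = 1.1e-19), the checkpoint kinases BUB1 3.21-fold and BUB1B 2.49-fold. All 7 metallothioneins and related genes fell (adjusted p = 6.2e-05), MT1X 3.19-fold and MT2A 3.0-fold, with the split between copies uncertain. FOXO targets had 9 rises and 3 falls (adjusted p = 0.00013; CCNG2 2.08-fold), p53 targets 7 and 1 (adjusted p = 0.0019; MDM2 1.33-fold), interferon genes 1 and 6 (adjusted p = 0.0036; IFI44L 3.78-fold lower) and neuron markers 1 and 4 (adjusted p = 0.011; TUBB3 2.95-fold lower). Metalloproteinase genes fell in 4 of 12 (adjusted p = 0.0043), the protease PLAU 2.98-fold, but this list was not called between the high and low doses. Autophagy genes rose in 11 of 18 (adjusted p = 0.00013, 11 with 1 fall adjusted over the list alone), SQSTM1 2.19-fold. Mitochondrially encoded genes fell in 12 of 13 (adjusted p = 0.0045, and adjusted p = 0.36 with an estimated correlation), at 4.366 to 5.708% of the counts (5.638 to 6.429% at the low dose). Immediate early genes had 2 rises and 9 falls (adjusted p = 0.018, 2 and 10 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation), matrix genes 4 and 12 (adjusted p = 0.021, 4 and 13 adjusted over the list alone; adjusted p = 0.34 with an estimated correlation). Histones fell in 6 of 9 (adjusted p = 0.034, 7 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation and 0.083 without the outlying library) and DNA replication in 5 of 20 (adjusted p = 0.04, and adjusted p = 0.31 with an estimated correlation), POLA1 2.48-fold. Cholesterol genes went both ways, 6 up (INSIG1 2.46-fold) and 6 down (HMGCS1 1.69-fold), and were not called as a list (adjusted p = 0.78). Astrocyte markers were not called either (adjusted p = 0.15), with 1 rise (NES 1.71-fold) and 5 falls, the glutamate transporter SLC1A3 being 2.99-fold lower.

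Between high and low doses of Paeoniae Radix 3902 genes rose and 3904 fell, 1265 of the 7806 by over 2-fold. MYOD1 again had 3 counts in the low-dose libraries, GDF15 rose 5.61-fold, and NDRG1 (ENSG00000104419, chromosome 8, 133237171 to 133302022), a hypoxia-induced gene, 4.93-fold from 49.97 ± 0.175 to 246.6 ± 10.5 CPM (log2 change 2.30 ± 0.06, adjusted p = 4.3e-30). DLGAP5 was 7.97-fold, CYP4V2 5.88-fold and MT1E 5.34-fold lower. Hypoxia genes rose in 17 of 19 (adjusted p = 1.1e-26; ADM 3.32-fold), ATF4 genes in 14 of 19 (adjusted p = 1.6e-16, 15 adjusted over the list alone) and autophagy genes in 12 of 18 (adjusted p = 4.8e-05, 13 adjusted over the list alone). NRF2 targets had 11 rises and 1 fall (adjusted p = 1.9e-09), FOXO targets 10 and 3 (adjusted p = 0.00012), p53 targets 8 and 1 (adjusted p = 0.00067, 8 and 2 adjusted over the list alone). NF-kB genes had 9 and 3 (adjusted p = 0.01, 9 and 4 adjusted over the list alone; adjusted p = 0.081 and a mean log2 change of -0.08, from 0.04, without replicate 2 of every group, and a mean of -0.06 without the filter), PTGS2 2.58-fold higher and CCL2 4.47-fold lower. Mitotic genes fell in 16 of 20 (adjusted p = 6.3e-12, 17 adjusted over the list alone), metallothioneins in 6 of 7 (adjusted p = 0.00011), and neuron markers in 3 of 6 with 1 rise (adjusted p = 0.0042). DNA replication fell in 10 genes (adjusted p = 0.0021, and adjusted p = 0.13 with an estimated correlation), and interferon genes had 2 rises and 6 falls (adjusted p = 0.0091, and adjusted p = 0.065 with an estimated correlation), IFI44L 4.5-fold lower.

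Cnidii Rhizoma at the high dose was followed by higher antioxidant and amino acid stress genes and lower mitotic, cholesterol and matrix genes than vehicle (n = 3 in both groups). HMOX1 rose 8.54-fold, from 84.88 ± 2.53 to 724.6 ± 43.6 CPM (log2 change 3.09 ± 0.08, adjusted p = 4.6e-28), GDF15 5.86-fold and SLC7A11 (ENSG00000151012, chromosome 4, 138164097 to 138242349) 4.29-fold from 101.5 ± 2.34 to 435.7 ± 6.19 CPM. The pseudogene NMRAL2P (5.93-fold) and the reductase genes AKR1C1 (4.11-fold) and AKR1B10 (4.05-fold) can share reads with relatives. TXNIP (ENSG00000265972, chromosome 1, 145992435 to 145996600), an inhibitor of thioredoxin, was 6.43-fold lower, at 1.705 ± 0.0816 against 11.0 ± 0.816 CPM (log2 change -2.69 ± 0.13, adjusted p = 4.2e-20). CCL2 was 4.16-fold and BIRC3 2.61-fold lower. In all 2514 genes rose and 2667 fell, 399 of the 5181 by more than 2-fold.

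NRF2 targets rose in 16 of 17 cases with Cnidii Rhizoma (adjusted p = 1.5e-86, 17 adjusted over the list alone). ATF4 genes had 17 rises and 1 fall (adjusted p = 1e-33, 18 and 1 adjusted over the list alone), the stress-induced DDIT4 3.17-fold, ASNS 3.06-fold and PSAT1 2.61-fold. All 20 mitotic genes fell (adjusted p = 2.1e-28), PLK1 by 0.91, AURKA by 0.75 and TPX2 by 0.66 on the log2 scale, and 14 of 20 replication genes (adjusted p = 6.5e-09), RRM2 1.63-fold. Cholesterol genes fell in 16 of 22 (adjusted p = 1.5e-16), INSIG1 2.25-fold and SQLE 1.49-fold, and matrix genes in 11 of 20 (adjusted p = 3.9e-09), CCN2 2.44-fold and ACTA2 1.94-fold. NF-kB genes had 2 rises and 10 falls (adjusted p = 6.1e-09, PTGS2 1.9-fold lower), and metalloproteinase genes 4 falls (adjusted p = 0.011, PLAU 1.82-fold). Neither list was called between the high and low doses. Hypoxia genes rose in 12 of 19 (adjusted p = 7.3e-08, 13 adjusted over the list alone; NDRG1 1.96-fold), autophagy genes in 9 of 18 (adjusted p = 0.00012, 12 adjusted over the list alone; SQSTM1 2.05-fold), PPAR targets in 4 of 10 (adjusted p = 0.0029; mean log2 change 0.13, and -0.03 without replicate 1 of every group; ANGPTL4 2.17-fold), and p53 targets in 5 with 2 falls (adjusted p = 0.0089, 6 and 2 adjusted over the list alone). Mitochondrially encoded genes fell in 12 of 13 (adjusted p = 6e-06, and adjusted p = 0.15 with an estimated correlation) and took 4.875 to 5.211% of the counts (4.909 to 5.624% at the low dose), MT-CO3 being 1.99-fold lower. ER chaperones rose in 5 of 15 (adjusted p = 0.0063, and adjusted p = 0.14 with an estimated correlation; DNAJB9 1.43-fold). Aryl hydrocarbon receptor targets had 1 rise and 4 falls (adjusted p = 0.0088, 1 and 5 adjusted over the list alone; adjusted p = 0.057 with an estimated correlation), SERPINB2 2.42-fold lower and ALDH3A1 3.84-fold higher. Histones fell in 4 of 9 (adjusted p = 0.037, 5 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation and 0.086 without the outlying library).

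Compared with its low dose, the high dose of Cnidii Rhizoma raised 1018 genes and lowered 1055, 137 of the 2073 by more than 2-fold. This count was 3638 without the outlying library and 3994 in a fit of the 6 libraries alone. HMOX1 rose 9.72-fold (log2 change 3.28 ± 0.09, adjusted p = 6.2e-29), GDF15 5.61-fold, NMRAL2P 5.49-fold and CHAC1 (ENSG00000128965, chromosome 15, 40952962 to 40956519) 3.68-fold. TXNIP was 5.55-fold, VAV3 2.25-fold and CCL2 2.15-fold lower. NRF2 targets rose in 16 of 17 (adjusted p = 3.1e-141, 17 adjusted over the list alone), ATF4 genes in 17 of 19 (adjusted p = 9.3e-75, 18 adjusted over the list alone; the amino acid transporter SLC7A5 2.35-fold), hypoxia genes in 11 of 19 (adjusted p = 3.5e-14, 14 adjusted over the list alone; VEGFA 1.41-fold) and autophagy genes in 10 of 18 (adjusted p = 6.6e-09, 11 adjusted over the list alone). ER chaperones rose in 8 of 15 (adjusted p = 1.1e-07, 11 adjusted over the list alone; HERPUD1 1.56-fold), PPAR targets in 2 of 10 (adjusted p = 2.5e-06, 3 adjusted over the list alone; ANGPTL4 3.46-fold) and p53 targets in 3 of 15 (adjusted p = 8.8e-05, 4 with 2 falls adjusted over the list alone). Falls covered 18 of 20 mitotic genes (adjusted p = 3.3e-26), 16 of 20 replication genes (adjusted p = 2.6e-23, 18 adjusted over the list alone), 15 of 22 cholesterol genes (adjusted p = 1.4e-20, 18 adjusted over the list alone), 8 of 20 matrix genes (adjusted p = 5.5e-07, 10 adjusted over the list alone) and 3 of 7 LXR targets (adjusted p = 0.00061, 4 adjusted over the list alone). Heat shock proteins fell in 1 of 12, HSPA8 1.1-fold (adjusted p = 0.048, 2 adjusted over the list alone; adjusted p = 0.31 with an estimated correlation), and interferon genes in 3 of 18, IFIT1 1.47-fold (adjusted p = 0.048, and adjusted p = 0.17 with an estimated correlation and 0.062 without the outlying library).

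With Rehmanniae Radix Preparata at the high dose (n = 2 against 3 vehicle libraries), aryl hydrocarbon receptor, NRF2 and PPAR targets rose, and cholesterol, hypoxia and ER chaperone genes fell. NPTX1 (ENSG00000171246, chromosome 17, 80467148 to 80477843), a secreted neuronal pentraxin, rose 3.8-fold, from 4.659 ± 1.04 to 17.61 ± 2.19 CPM (log2 change 1.92 ± 0.16, adjusted p = 1.6e-11). Thrombomodulin gene THBD (ENSG00000178726, chromosome 20, 23045633 to 23049741) rose 2.33-fold, the growth factor binding protein gene IGFBP1 2.2-fold and the efflux transporter gene ABCG2 2.09-fold to 66.56 ± 0.179 CPM. MT1E (ENSG00000169715, chromosome 16, 56625475 to 56627112) was 2.1-fold lower, ZSWIM4 and IL33, a cytokine, 1.82-fold and HERPUD1, of ER-associated degradation, 1.81-fold. In all 1187 genes rose and 1450 fell, 139 of the 2637 by more than 2-fold. The count was 4711 without the outlying library, 5214 in a fit of the 5 libraries alone, and 1163 and 1466 without high replicates 1 and 2.

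Aryl hydrocarbon receptor targets rose in 6 of 7 cases with Rehmanniae Radix Preparata (adjusted p = 5.5e-11, 6 with 1 fall adjusted over the list alone), the cytochrome genes CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610) 3.53-fold to 3.204 CPM from 0.9051 ± 0.181 and CYP1B1 1.89-fold to 235.6 ± 0.537 CPM. NRF2 targets rose in 8 of 17 (adjusted p = 7.1e-10, 10 adjusted over the list alone; NQO1 1.77-fold), PPAR targets in 5 of 10 (adjusted p = 8.2e-06, 7 adjusted over the list alone; PDK4 2.89-fold), and glucocorticoid receptor targets in 3 with 2 falls (adjusted p = 0.0032, 4 and 2 adjusted over the list alone; SGK1 1.48-fold). Cholesterol genes fell in 12 of 22 (adjusted p = 1.6e-10, 13 adjusted over the list alone; INSIG1 1.46-fold), mitotic genes in 10 of 20 (adjusted p = 8.4e-10; PLK1 by 0.53 on the log2 scale), hypoxia genes in 8 of 19 (adjusted p = 6.9e-08, 10 adjusted over the list alone; the mitophagy receptor BNIP3 1.69-fold) and ER chaperones in 5 of 15 (adjusted p = 1.9e-05, 9 adjusted over the list alone). Astrocyte markers fell in 5 of 9 (adjusted p = 0.0041, 5 with 1 rise adjusted over the list alone; mean log2 change -0.14, and 0.03 without the filter), SOX9 1.31-fold. That list was not called between the high and low doses. Matrix genes had 1 rise and 9 falls (adjusted p = 3.2e-06, 1 and 10 adjusted over the list alone). Fatty acid synthesis fell in 5 of 10 (adjusted p = 0.00027, 7 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation), SCD 1.63-fold. Mitochondrially encoded genes fell in 5 of 13 (adjusted p = 0.00029, 7 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation), at 5.548 to 5.725% of the counts (4.884 to 5.89% at the low dose). Metallothioneins fell in 3 (adjusted p = 0.018, and adjusted p = 0.11 with an estimated correlation), and ATF4 genes had 1 rise and 6 falls (adjusted p = 0.043, 1 and 7 adjusted over the list alone; adjusted p = 0.35 with an estimated correlation and 0.057 without the outlying library).

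The high dose of Rehmanniae Radix Preparata differed from the low dose in 165 genes, 64 lower and the rest higher, 14 of them over 2-fold. NPTX1 rose 3.24-fold (log2 change 1.70 ± 0.18, adjusted p = 4.4e-08), CXCL8 2.45-fold and THBD 2.33-fold. MT1E was 1.94-fold, SCD 1.74-fold and SREBF1 1.69-fold lower. Lists that rose were aryl hydrocarbon receptor targets (4 of 7; adjusted p = 1.3e-23, 6 adjusted over the list alone; TIPARP 1.68-fold), PPAR targets (4 of 10; adjusted p = 5.2e-14, 5 adjusted over the list alone), NRF2 targets (4 of 17; adjusted p = 8.6e-13, 5 adjusted over the list alone), NF-kB genes (5 of 16; adjusted p = 2.1e-11; LIF 2.0-fold), glucocorticoid receptor targets (3 of 11; adjusted p = 1.5e-06, 4 adjusted over the list alone) and metalloproteinase genes (2 of 12; adjusted p = 0.0018, 4 with 1 fall adjusted over the list alone; PLAU 1.4-fold). Lower were cholesterol genes (5 of 22; adjusted p = 3e-19, 14 adjusted over the list alone; LSS 1.27-fold), hypoxia genes (5 of 19; adjusted p = 1.8e-14, 12 adjusted over the list alone; PFKFB4 1.37-fold), fatty acid synthesis (2 of 10; adjusted p = 5.8e-08, 3 adjusted over the list alone) and DNA replication (2 of 20; adjusted p = 4.2e-07, 4 adjusted over the list alone). So were ER chaperones (2 of 15; adjusted p = 1.3e-06, 3 adjusted over the list alone; HSPA5 1.27-fold), LXR targets (1 of 7; adjusted p = 4.4e-06, 2 adjusted over the list alone), interferon genes (1 of 18; adjusted p = 0.00076, 2 adjusted over the list alone; adjusted p = 0.5 without replicate 2 of every group; IFIT3 1.3-fold) and metallothioneins (1 of 7; adjusted p = 0.0021, 2 adjusted over the list alone). Matrix genes fell in 1 case (adjusted p = 0.0013, 5 adjusted over the list alone; adjusted p = 0.18 with an estimated correlation) and immediate early genes rose in 1 (adjusted p = 0.016, 2 adjusted over the list alone; adjusted p = 0.11 with an estimated correlation). Calls with no member past the threshold over all genes were histones (higher, 2 adjusted over the list alone, adjusted p = 0.013, adjusted p = 0.062 with an estimated correlation), mitosis (lower, 1 adjusted over the list alone, adjusted p = 0.019, adjusted p = 0.084 with an estimated correlation), mitochondrially encoded genes (higher, adjusted p = 0.03, adjusted p = 0.49 with an estimated correlation, and lower without replicate 1 of every group, adjusted p = 0.71, with the mean log2 change at -0.04 from 0.15), microglia markers (lower, adjusted p = 0.03, adjusted p = 0.082 with an estimated correlation, and adjusted p = 0.38 without the filter with the mean log2 change at 0.20 from -0.14) and autophagy (lower, adjusted p = 0.033, adjusted p = 0.28 with an estimated correlation). The 165 calls became 516 without the outlying library, 78 and 79 without high replicates 1 and 2, and 66 and 92 without low replicates 1 and 2. In the same order MT1E had an adjusted p of 0.3, 0.2, 0.2 and 0.17.

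**Figure D2:**
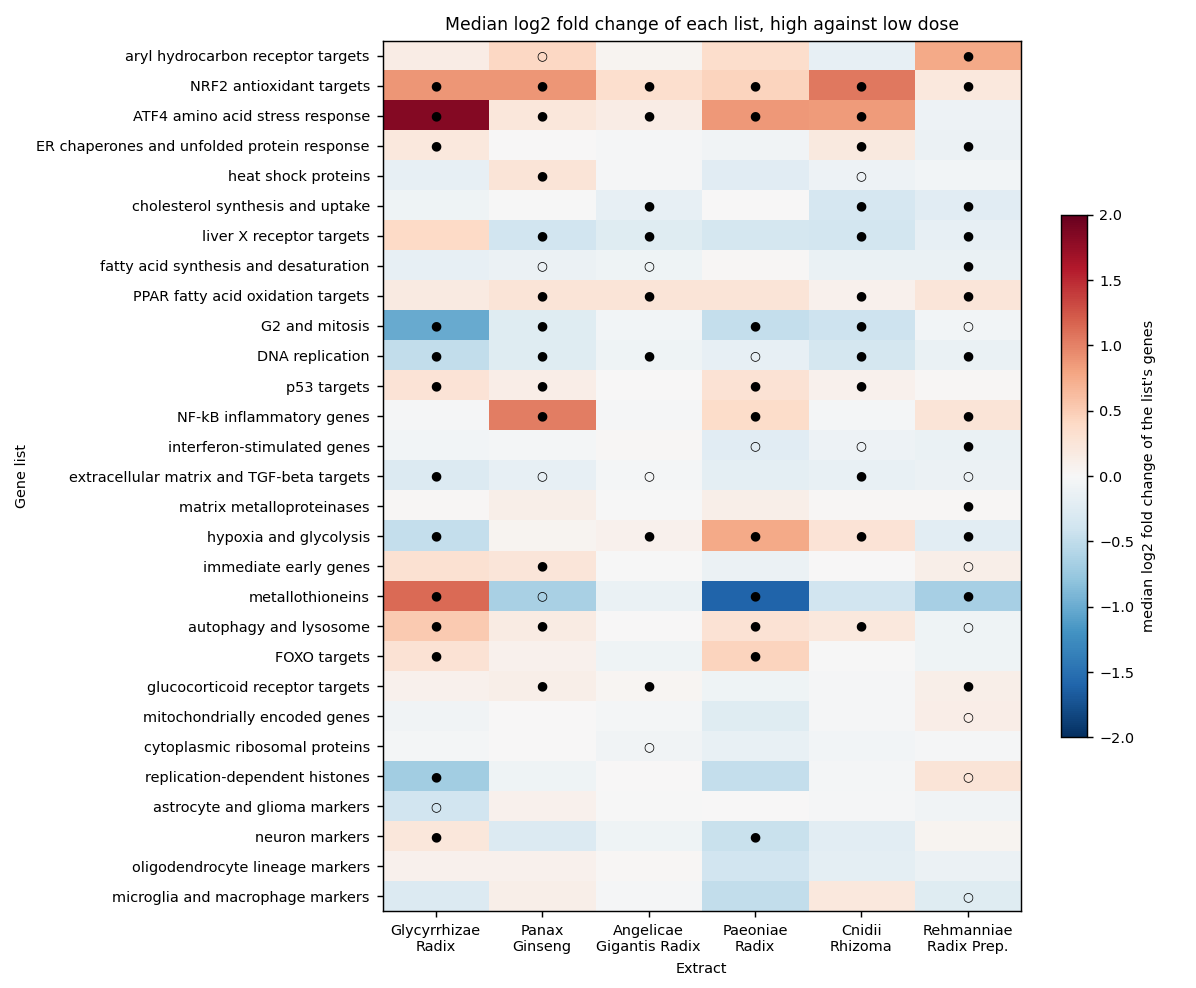
Median log2 change of 29 gene lists between the high and low doses of 6 extracts; colours run from lower (blue) to higher (red), filled circles mark lists called also with an estimated correlation, and open circles those called only with the preset one. For neuron markers with Glycyrrhizae Radix, called lower, the median is 0.22, against the sign of the test.

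Oligodendrocyte lineage markers were called with no extract, at adjusted p = 0.78, 0.8, 0.42, 0.24, 0.43 and 0.59 against vehicle and 0.89, 0.94, 0.93, 0.29, 0.25 and 0.6 between doses, in the order in which the extracts are given above. Of 174 list tests against vehicle 89 were called, 63 of them also with an estimated correlation, and of 174 between doses 88 and 69, 3 of these at adjusted p = 0.0496 to 0.0499.

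At the medium dose, NEAT1 was among the largest rises against vehicle with 4 extracts, and the inflammatory genes LIF, CCL2 and PTGS2 among the falls. Glycyrrhizae Radix changed 3046 genes (1386 higher, 1660 lower), with NEAT1 2.74-fold and the kinase MARK2 2.31-fold higher and PTGS2 2.31-fold, LIF 2.15-fold and CCL2 2.11-fold lower. Panax Ginseng changed 2348 (1066 and 1282), AKR1B10 2.38-fold and TNFRSF25 2.31-fold upward, CCL2 1.99-fold downward. For Angelicae Gigantis Radix the count was 5997 (3294 and 2703), with ZSWIM4 2.34-fold and the mitochondrial MT-ATP8 2.06-fold lower; RGPD5 (6.63-fold), RN7SL2 (5.35-fold) and MVP-DT (3.71-fold) upward and BIVM-ERCC5 (5.29-fold) downward are multicopy or overlapping genes. In a fit of its libraries and vehicle alone these 6 genes had an adjusted p of 0.34 to 0.45, and RGPD5 one of 0.05 to 0.11 without vehicle replicate 1, 2 or 3 or its own replicate 1 or 3. Paeoniae Radix changed 2001 (811 and 1190), TNFRSF25 2.26-fold upward and MT1E 2.18-fold downward. Cnidii Rhizoma changed 3021 (1321 and 1700), AKR1B10 2.62-fold and NEAT1 2.29-fold upward, CCL2 2.15-fold and LIF 2.07-fold downward. Rehmanniae Radix Preparata changed 2047 (861 and 1186), NEAT1 2.25-fold upward and SAMD4A 1.82-fold and ZSWIM4 1.81-fold downward. Without the outlying library the counts were 5354, 4508, 3486, 4145, 5165 and 4148 in this order, and in fits of the compared libraries alone 4868, 4134, 0, 4924, 5654 and 4801. The 0, for Angelicae Gigantis Radix, is from edgeR, with 1722 genes at an unadjusted p under 0.05 and 234 called by DESeq2. Panax Ginseng had 1561 calls without vehicle replicate 1 and 1423 without its own replicate 3. Paeoniae Radix had 1310 and 1316 without the libraries of the same names, and Rehmanniae Radix Preparata 930 and 891 without its replicates 1 and 2.

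At the low dose NEAT1 rose 2.32-fold against vehicle with Glycyrrhizae Radix and Panax Ginseng, 2.11-fold with Paeoniae Radix, 2.23-fold with Cnidii Rhizoma and 2.13-fold with Rehmanniae Radix Preparata. CXCL8 was 1.88-fold lower with Glycyrrhizae Radix, 2.19-fold with Panax Ginseng, 2.08-fold with Angelicae Gigantis Radix, 1.81-fold with Paeoniae Radix and 2.06-fold with Rehmanniae Radix Preparata. In the order of the medium dose, the counts were 2377 (1024 higher, 1353 lower), 2196 (1003, 1193) and 1793 (699, 1094). Then followed 1604 (684, 920), 2590 (1109, 1481) and 1803 (717, 1086). In this order they were 4496, 4341, 3857, 3549, 4860 and 3795 without the outlying library and 5160, 3368, 3552, 3690, 5569 and 3943 in fits of the compared libraries alone. Without vehicle replicate 1, Panax Ginseng had 1443, Angelicae Gigantis Radix 1041 and Paeoniae Radix 985 calls, and without vehicle replicate 3 Angelicae Gigantis Radix had 1194. Without their own replicate 3 the counts were 1047 for Angelicae Gigantis Radix, 979 for Paeoniae Radix and 1702 for Cnidii Rhizoma, and Rehmanniae Radix Preparata had 778 and 925 without replicates 1 and 2.

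**Figure D3:**
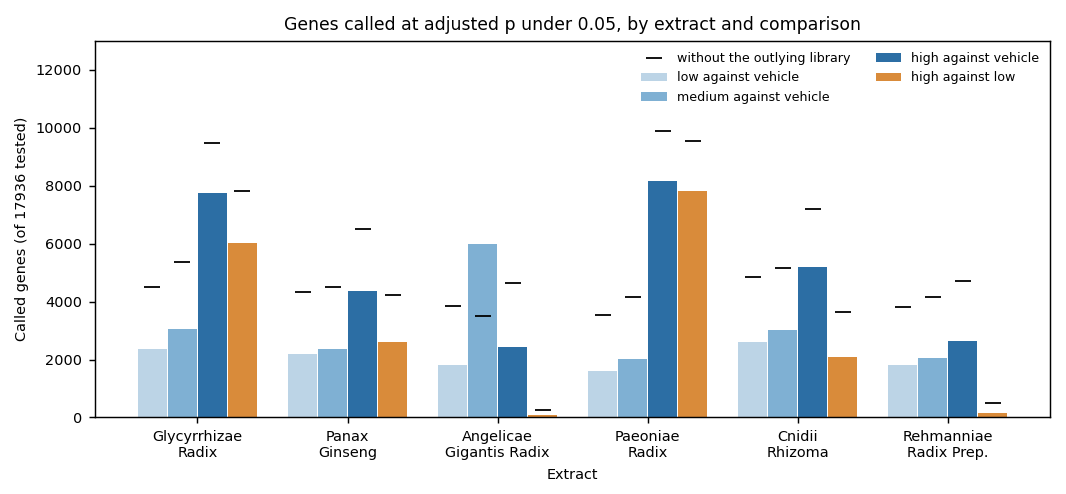
Number of genes called (edgeR, adjusted p under 0.05) for 6 extracts; light to dark blue bars are the low, medium and high dose against vehicle, orange bars the high against the low dose, and black ticks the same counts without the outlying library. Between doses the counts run from 91 to 7806.

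A large set of genes differed from vehicle at every low dose. Of the genes tested, 285 were higher and 518 lower with all 6 extracts at the low dose, among them NEAT1, against 0 in 4 simulations of unchanged groups that share the vehicle libraries, none of which called a gene, and 0.00021 and 0.0014 for independent lists, which leave out the shared vehicle. Without the outlying library the numbers were 588 and 1112. The covariance of the log2 changes over the 15 pairs of extracts averaged 0.121 against 0.0647 in the simulations, a difference of 0.0566. The 3 vehicle libraries used here could not be split, so part of the excess may come from the shared controls. Low doses compared with each other, by contrast, differed in 0 to 31 genes (edgeR, 532 to 1695 genes at an unadjusted p under 0.05, 1 to 136 by DESeq2). Within a set these counts were 1 for Glycyrrhizae Radix and Panax Ginseng and 0 for the pairs of the other sets, where DESeq2 called 3 and 2. Without the outlying library the counts within sets were 5, 7 and 4. Glycyrrhizae Radix and Panax Ginseng then differed from the extracts of the other sets in 219 to 665 genes, and the other sets from each other in 2 to 41.

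**Figure D4:**
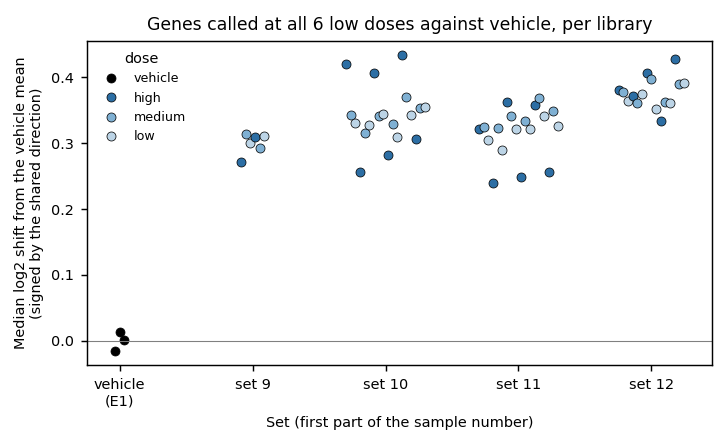
Median log2 shift from the vehicle mean, signed by direction, of the genes called in the same direction at all 6 low doses, for each of 60 libraries by set. The vehicle libraries lie at -0.015 to 0.014 and the 57 treated libraries at 0.239 or above. The same vehicle libraries served to choose the genes and as the reference, so these positions are partly built in.

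Part of the calls against vehicle were also called, in the same direction, between high and low dose. The share was 75% for Paeoniae Radix (6122 genes), 63.6% for Glycyrrhizae Radix (4918), 39.8% for Panax Ginseng (1740), 30.4% for Cnidii Rhizoma (1574), 4.63% for Rehmanniae Radix Preparata (122; 7.47% without the outlying library) and 2.81% for Angelicae Gigantis Radix (68). Without the outlying library the last 4 counts were 2814, 2710, 352 and 181. Opposite calls numbered 28, 21, 31, 20, 2 and 4. Both comparisons use the same high-dose libraries, which alone raises such counts. Independent lists would share 1776, 1302, 315.5, 299.6, 11.86 and 6.091. Changes between high and low dose, which do not share libraries across extracts, were compared by their correlation across genes, which are not independent replicates. Of 15 pairs, picked here for having the highest value, Glycyrrhizae Radix and Cnidii Rhizoma had r = 0.35 (Spearman coefficient 0.45) and shared 758 rises and 829 falls, with 75 genes going opposite ways and 180.2 and 167.9 shared by independent lists. That r was 0.70 over genes with a mean of at least 5 CPM and 0.22 without replicate 1 of each group. Glycyrrhizae Radix and Paeoniae Radix had r = 0.14 (Spearman coefficient 0.18) with 1268 and 1193 shared and 1088 opposite.

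Extracts of the same set were compared with each other at the high dose. Glycyrrhizae Radix, at 300 µg/mL, differed from Panax Ginseng, at 500 µg/mL, in 6779 genes (3467 higher, 3312 lower), 996 of them over 2-fold. KCP was 23.1-fold and GDF15 14.5-fold higher with Glycyrrhizae Radix, and TUBB4A was 42.7-fold and CXCL8 8.65-fold lower. Angelicae Gigantis Radix differed from Paeoniae Radix in 7648 genes (3773 higher, 3875 lower), 1262 over 2-fold. DLGAP5 was 8.09-fold and CYP4V2 5.98-fold higher with Angelicae Gigantis Radix, while MYOD1 was far lower and APLN 5.25-fold. Cnidii Rhizoma and Rehmanniae Radix Preparata differed in 1907 genes (967 higher, 940 lower), 199 over 2-fold, with HMOX1 8.46-fold and GDF15 4.87-fold higher with Cnidii Rhizoma. The protease inhibitor gene SERPINB2 was 3.25-fold and NPTX1 2.82-fold lower. The last count was 3285 without the outlying library, 3418 in a fit of the 5 libraries alone, and 1068 and 1034 without Rehmanniae Radix Preparata high replicates 1 and 2.

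Poria Cocos and Atractylodis Rhizoma had 1 library per dose, labelled replicate 3 (others were not analysed here), so their values have no replicate check and no test. With Poria Cocos the transcription factor gene EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315) stood at log2 changes of 1.15, 0.74 and 0.48 from vehicle at the high, medium and low dose, reaching 45.22 CPM against 20.32 ± 1.67 in vehicle. NPTX1 was at 1.11, UGT1A7, a glucuronosyltransferase, at 1.07, AKR1C1 at 1.00 and NQO1 at 0.99 at the high dose. MT1E stood at -1.18, HERPUD1 at -1.03 and RRAD at -0.84. With Atractylodis Rhizoma the amino acid transporter genes SLC7A8 (ENSG00000092068, chromosome 14, 23125295 to 23183674) and SLC7A11 stood at 1.09 and 1.07, SLC7A11 with 213.2 CPM. AKR1C2 was at 1.01 and MARK2 and AKR1C1 at 0.95. Lower were CCL2 at -1.10, the keratin gene KRT18 at -1.07 and ZSWIM4 at -0.94. Against the 17 low-dose libraries of the other extracts, a reference chosen after the data were seen, SLC7A11 stood at 1.00, KRT18 at -1.04 and NPTX1 at 1.07. EGR1 was at 0.64, HERPUD1 at -0.47, SLC7A8 at 0.68, AKR1C2 at 0.57, AKR1C1 at 0.66 with Poria Cocos and 0.61 with Atractylodis Rhizoma, MARK2 at 0.00, ZSWIM4 at -0.19 and CCL2 at -0.26. At all 3 doses 48.9% of 11182 genes for Poria Cocos and 50.8% of 11196 for Atractylodis Rhizoma lay outside the range of the vehicle libraries on the same side, where chance gives 10% only if vehicle is not set apart from all other libraries. Outside the wider range of the low-dose libraries lay 349 and 152 genes. Among lists, heat shock proteins lay among the highest 2.5% of 10000 random lists at all doses with Poria Cocos against vehicle (median log2 change 0.08, 0.10 and 0.06), but not against the low-dose libraries (0.04, 0.04 and 0.03, percentiles 90.4, 90.8 and 70.5). Mitotic genes (-0.31, -0.16 and -0.16) and NF-kB genes (-0.32, -0.29 and -0.61) lay among the lowest 2.5% with Atractylodis Rhizoma against vehicle. Against the low-dose libraries mitotic genes did so at the high dose only (-0.12, 0.03 and 0.04, percentiles 0, 84.5 and 96.1) and NF-kB genes at the low dose only (0.00, 0.01 and -0.13, percentiles 48.4, 62.1 and 0.02).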

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

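The tests of the outlying library and of MYOD1 were chosen after the result was seen; those of the offset from vehicle and the splits of libraries were set down first. Extracts of the same set differed at the high dose by a direct test, in 6779, 7648 and 1907 genes (order of the results).

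For 3 against 3 libraries only 10 splits exist, too few for a share under 0.05, so only the real count and the highest of the other splits are given, from fits of the 6 libraries alone. In all comparisons below but 1, only 1 split, the real one, gave as many genes. The real counts against vehicle at the high dose were 9467, 6505, 4294, 9323 and 7457 (Glycyrrhizae Radix, Panax Ginseng, Angelicae Gigantis Radix, Paeoniae Radix and Cnidii Rhizoma), with 0 or 1 in other splits. At the medium dose they were 4868, 4134, 0, 4924 and 5654, with 0 or 1; for the 0, of Angelicae Gigantis Radix by edgeR (1722 genes at an unadjusted p under 0.05, 234 by DESeq2), all 10 splits gave 0. Counts at the low dose were 5160, 3368, 3552, 3690 and 5569, with at most 3, and between doses 7818, 3009, 81, 8829 and 3994, with at most 9, for Angelicae Gigantis Radix. Pairs of extracts gave 8230 and 8299, with 0.

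Every low dose differed from vehicle in many of the same genes, 285 higher and 518 lower with all 6 extracts. An effect that grows with dose would move such genes further from low to medium dose, but over the 1732 to 1895 genes called at the low dose of the other 5 extracts (without the outlying library) the largest median shift was 0.023 on the log2 scale (0.021 over the shared 803), under the bound of 0.1, which argues against it. A trend on transcript length and GC content left 604 of 802 genes called at all 6 low doses after its removal (75.3%, exact binomial 95% interval 72.2 to 78.3%, against a bound of 75%) and the median shift at 0.32 against 0.34 before, which argues against it as the whole cause and leaves a part open. Something that sets the vehicle libraries apart may account for it. The 6 single-library samples lay on the same side (median 0.3, 0.27 to 0.31, against 0.34 at the low doses). This cannot decide it, since the genes were chosen and measured against the same vehicle libraries. Set, culture and solvent of the vehicle, and an effect of all extracts already complete at the low dose, cannot be told apart. The vehicle forms a set of its own by sample numbers, though the titles name 1 batch.

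Replicate 2 of Angelicae Gigantis Radix at the medium dose had 1571 of 11234 genes over 2-fold from its fellow libraries. A trend on length and GC content brought 21.3% of these within 2-fold, leaving 1236, so it can account for a part only. Of 14 genes at 5 CPM or more and over 4-fold above every other library, 13 overlap an expressed gene on the opposite strand (92.9%), against 2532 of 10996 other genes (23%; Fisher's exact test, one-sided, p = 5.8e-08), so reads counted without regard to strand in this library are a candidate explanation for such genes; over 88 antisense genes the median shift was only 0.04, and 23 readthrough genes lay at -0.76. RNA of other cells stays open, with 3 genes above 1 CPM here and under 0.1 CPM elsewhere (1 at most in another library), none of them protein-coding, summed markers of neurons at 217 CPM (85.1 to 184 elsewhere) and epithelium at 275 (105 to 226), and of oligodendrocytes at 91.7 (163 to 216), microglia at 118 (137 to 253) and endothelium at 17.1 (30.9 to 43.2). No biological explanation was tested, since the fellow libraries carry the same label.

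MYOD1 reached 71.2 CPM with Paeoniae Radix at the high dose, with at most 3 counts in each of the other 57 libraries. Muscle cells in the cultures would bring abundant muscle transcripts, but the highest marker, MYH3, was at 0.656 CPM. Reads of related genes are argued against by a summed count of 0 for MYF5, MYF6 and MYOG in these libraries. Transcription from a neighbour would raise a gene within 100 kb by as much, but the largest change was 1.83 on the log2 scale, for KCNC1 (29 against 8 counts). An induction of MYOD1 in these cells stays as a hypothesis; of 6 targets of this factor, CHRNA1 (41 against 0 counts) and CDH15 (46 against 4) were higher, KLHL41 had 67 against 25 but 56 at the low dose, MYOG, MYMK and CHRND had 0, and a source outside the culture, such as a plasmid, was not tested.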

How the results depend on the processing

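Leaving out the outlying library, robust fitting and the low-dose reference were chosen after the result was seen; the other alternatives were planned. No count or named gene reversed under any of them. Scaling by relative log expression kept all 30 results within 1.5 times (99.5 to 102% of the reported count), as did the DESeq2 Wald test (27 results, 98.4 to 126%), robust fitting (27, at least 98.2%) and the replicate block (30, 97.6 to 111%). The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.049 to 0.136, in 0 of 27 comparisons with every pair over 0.1, though in 7 of those with 3 pairs every library fitted its own number best. The block took 5 of 177 list calls to an adjusted p of 0.051 to 0.06 and added 1. Of 530 named genes in comparisons, 0 lost their call under relative log expression or without the outlying library, 3 under DESeq2, 7 without the filter, 1 with the block, 2 with robust fitting, 6 in fits of the compared libraries alone and 38 when some library was left out.

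Without the outlying library 20 of 31 results moved by over 1.5 times. Against vehicle, the high doses then gave 4635 for Angelicae Gigantis Radix and 4711 for Rehmanniae Radix Preparata. In the order of the extracts in the results, the medium doses gave 5354, 4508, 3486, 4145, 5165 and 4148. The low doses gave 4496, 4341, 3857, 3549, 4860 and 3795. High against low dose gave 4236 for Panax Ginseng, 249 for Angelicae Gigantis Radix, 3638 for Cnidii Rhizoma and 516 for Rehmanniae Radix Preparata; Cnidii Rhizoma against Rehmanniae Radix Preparata gave 3285, and the highest count between low doses was 665 against 31. Fits of the compared libraries alone gave 4294 for Angelicae Gigantis Radix and 5214 for Rehmanniae Radix Preparata at the high dose. The medium doses in the same order gave 4868, 4134, 0, 4924, 5654 and 4801, the 0 by edgeR with 1722 genes at an unadjusted p under 0.05 and 234 by DESeq2. At the low doses the counts were 5160, 3368, 3552, 3690, 5569 and 3943, for Cnidii Rhizoma high against low 3994, and for it against Rehmanniae Radix Preparata 3418. Without the filter on low counts, Angelicae Gigantis Radix high against low gave 165. The correlation of Glycyrrhizae Radix and Cnidii Rhizoma was 0.70 over genes with a mean of at least 5 CPM, against 0.35. For the single libraries, 501 values lay outside the low-dose range, the wider one, against 11151 outside the vehicle range. The cause was not tested for the outlying library, the fits of the compared libraries alone, the filter or the correlation.

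Leaving out each library in turn gave these ranges of calls, in the order above. Against vehicle they were 6848 to 6942, 3397 to 3706, 1657 to 1937, 7233 to 7415, 4118 to 4434 and 1163 to 2161 at the high dose. At the medium dose they were 2157 to 2411, 1423 to 1950, 3486 to 7974, 1310 to 1597, 2165 to 2414 and 891 to 1651, and at the low dose 1589 to 1821, 1443 to 1662, 1041 to 1388, 979 to 1357, 1702 to 2034 and 778 to 1384. Between doses they were 5200 to 5384, 1978 to 2143, 49 to 79, 6884 to 7060, 1496 to 1629 and 66 to 92, and for the pairs of extracts 5884 to 6009, 6746 to 6938 and 1034 to 1544. Leaving out 1 of 2 libraries of Rehmanniae Radix Preparata left 1, taken to vary like the other groups. The libraries that moved a count by over 1.5 times are named with their values in the results; for the widest range it is the outlying library, replicate 2 of Angelicae Gigantis Radix at the medium dose (3486). The called lists were 86 to 90 against vehicle and 83 to 90 between doses, and the correlation 0.22 to 0.28, without replicate 1, 2 or 3 of every group. Those omissions cost 14, 10 and 9 of 177 list calls and added 6, 13 and 4, and the direction turned once, for mitochondrially encoded genes with Rehmanniae Radix Preparata between doses without replicate 1. An estimated correlation cost 45 list calls, the absence of a filter 4, adding 35 and with 5 means changing sign, and the absence of the outlying library 6, the last adding 17. The simulation given above changed few genes.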

Other observations

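The tests of zinc-related genes were chosen after the result was seen. Metallothioneins, which bind zinc and copper, moved apart between extracts, all 7 genes of the list lower with Paeoniae Radix and higher with Glycyrrhizae Radix at the high dose against vehicle. A candidate explanation is less available zinc in the first and more in the second. The zinc importer gene SLC39A10, known to move against the metallothioneins, was then looked at between high and low dose. It was higher with Paeoniae Radix (log2 change 0.93, adjusted p = 1.5e-13) and lower with Glycyrrhizae Radix (-0.90, adjusted p = 1.3e-12), while the exporter gene SLC30A1, a member of the list, stood at -0.49 and 0.44. This stays a hypothesis, since zinc was not measured and other factors also act on these genes.

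Against the 17 low-dose libraries, aryl hydrocarbon receptor targets with Poria Cocos had median log2 changes of 0.72, 0.41 and 0.13 at the high, medium and low dose, the first at percentile 100 of random lists. Against vehicle these were 0.46, 0.16 and -0.06 (percentiles 100, 97.2 and 27.6). At the high dose NRF2 targets stood at 0.34 (0.47 against vehicle) and ER chaperones at -0.30 (-0.36; percentile 0). With Atractylodis Rhizoma, NRF2 targets stood at 0.46 (0.66) and ATF4 genes at 0.24 (0.19), all at percentile 100. These were picked from 14 of 29 lists with Poria Cocos and 13 with Atractylodis Rhizoma among the highest or lowest 2.5% at the high dose (9 and 13 against vehicle). The libraries are single, and the low-dose reference was chosen after the data were seen.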
